A study of Mus musculus with 10 samples.

How the data were processed

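Total RNA from 10 mouse intestinal organoid samples, 5 labelled KO for IκBα and 5 WT, was measured on 1 array each. Per the labels' protocols, 100 ng of RNA was labelled with biotin by the GeneChip WT PLUS method. The authors deposited 1 log2 level per probe set and array, made with RMA per the submitters' processing notes, which also name limma. Whether the arrays were normalized together is not given in the sources used here, and neither are versions or a genome build. The table held 28846 probe sets, of which 6640 were controls. Of the other 22206, 19572 were paired with 1 gene symbol, 0 with several and 2634 are unnamed here. All 19572 matched a gene identifier of the mouse RefSeq table (assembly GRCm38.p6), which was used for names only. Scanner files and detection calls were not used here, so no gene was called absent. The age or passage mark in the labels was not interpreted. The number of arrays limits precision; the median SD of a probe set was 0.20 in KO and 0.21 in WT, and the first principal component held 73.6% of the variance and the second 8.58%.

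The deposited log2 levels were taken as they were. KO and WT were compared with limma (version 3.58.1, R 4.3.3) by a linear model with moderated variances, fitted on all 28846 probe sets. P-values were adjusted by the Benjamini-Hochberg method over the 19572 probe sets with 1 symbol, with a threshold of 0.05. These stood for 19505 genes, and 55 genes had more than 1 probe set; 0 of these had probe sets changed in opposite directions and 8 had a changed beside an unchanged one. For lists and names, the probe set with the highest mean over the 10 arrays stood for its gene. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

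30 marker lists were written from general knowledge of the field before the data were examined, with 846 entries, 798 distinct genes and 727 of them measured. They covered fetal intestinal epithelium, adult stem cells, NF-kB, interferon, YAP, Wnt and Notch genes, the epithelial cell types, enterocyte maturation, metabolism, proliferation, polycomb and Hox genes, regions of the gut, non-epithelial cells, stress, and junctions with keratins. Some lists shared genes. The adult stem cell and Wnt lists shared 10, and the absorptive enterocyte list shared 5 with the weaned and 4 with the proximal list. The weaned and xenobiotic lists shared 3, as did the suckling and distal lists, and other pairs shared fewer. Each list was tested against all other genes with limma's camera at a preset correlation between genes of 0.01, adjusted over the 30 lists. Beside it stood camera with an estimated correlation, and fry, whose directional test asks for movement to 1 side and whose mixed test for movement to any side. Counts adjusted over the list alone used the limma p-values of its members only. A further check list held sex-linked genes, and 7 more lists were written after the data were seen. Their set tests ran on members whose values had not been seen before, adjusted among themselves, and for the X-linked list on all members as well. For the array-level comparison, each gene was centred on its mean over the 10 arrays and averaged over the fetal or the adult list. Groups were compared by an exact two-sided permutation test, adjusted over the 3 comparisons.

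The rule for named genes was fixed with the lists. It took Nfkbia, the 12 highest and the 12 lowest changes among genes that passed with no overlap of groups, the 4 members of each list with the smallest p, the sex-linked list, and a set of markers named in advance. Predicted genes and olfactory and vomeronasal receptors were counted but not named. Genes outside the rule are said to have been named after their values were seen.

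Alternatives changed the normalization (cyclic loess, or centring on the 75th percentile), left out the dimmest probe sets, changed the variance model, weighted arrays, left out each array in turn, widened the adjustment to all probe sets, averaged the probe sets of a gene, tested against a 1.2-fold change with limma's treat, or scaled genes to unit SD. 3 more were added after the data were seen: control probe sets left out, X and Y probe sets left out, and KO replicate 2 with WT replicate 4 left out. A value far from the other 4 of its group was sought by Dixon's ratio of gap to range. The scripts were tested on simulated data with 200 changed genes among 19572 probe sets. In the KO against WT step, 30% of genes changed by 0.5 on the log2 scale were recovered, 74% by 1, 98% by 2 and 100% by 4, with 7 false calls among 158. The list step recovered the 1 shifted list and called 0 others. Genes were simulated independently of each other, so this did not test the preset correlation where genes move together. Far fewer genes were changed here than the 5224 probe sets that passed in the data, so these recovery rates need not hold there.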

Results

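Gene expression was measured in mouse intestinal organoids, which are miniature epithelia grown in culture from intestinal tissue. 5 arrays came from samples labelled knockout (KO) for IκBα and 5 from wild type (WT) samples. IκBα, the product of Nfkbia, binds NF-kB transcription factors and keeps them out of the nucleus. The title of the series asks whether its loss gives intestinal stem cells a fetal phenotype, so KO was compared with WT for single genes, for lists of marker genes, and for a fetal and an adult stem cell level in each array. The median level per array lay between 6.42 and 6.56 on the log2 scale. Pearson's r across probe sets, which are not independent replicates, was 0.968 to 0.988 between KO arrays, 0.961 to 0.993 between WT arrays and 0.855 to 0.909 between the groups. The labels do not say whether the samples came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. All levels and changes below are on the log2 scale, and a change is KO minus WT.

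Nfkbia was lower in every KO array, at 5.06 ± 0.31 (SD, n = 5) against 9.19 ± 0.38 (SD, n = 5) in WT. The change was -4.13 with a standard error of 0.20, or 17.5-fold (limma, adjusted p = 2.81e-08). The KO level lay within the range of the negative control medians, which were 4.30 to 5.10 in the 10 arrays, so this size is a lower bound. Which part of the gene was deleted, and where the probes lie, are not given in the sources used here. 3 transcripts of the Y chromosome separated the groups as well. Eif2s3y changed by -5.20, Uty by -4.47 and Kdm5d by -2.42, and each was lower in all 5 KO arrays than in all 5 WT arrays (limma, adjusted p at most 7.72e-05). Lower Y-linked signal therefore went with the KO label, and so with every difference between KO and WT described here.

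**Figure D1:**
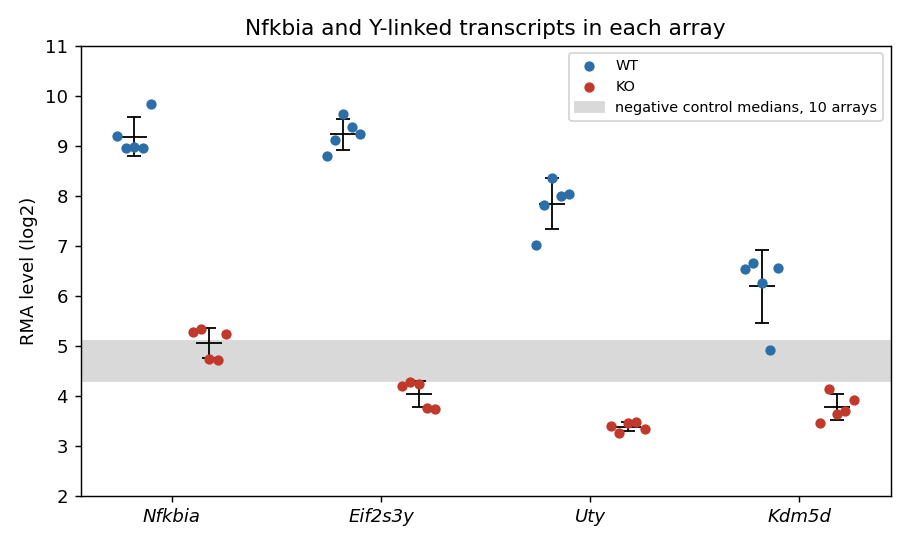
RMA level (log2) of Nfkbia and of 3 Y-linked transcripts in each of the 5 WT and 5 KO arrays; bars give the mean and SD, and the grey band spans the negative control medians of the 10 arrays. All 4 transcripts were lower in every KO array than in every WT array.

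The 12 highest changes held some genes of secreted defence and matrix proteins, and the 12 lowest held genes of Paneth cells and of absorptive enterocytes, the antimicrobial and the nutrient-absorbing cells of the small intestine. Whether such groups moved as a whole was tested by list. The 12 highest changes included Gabrp, a subunit of a GABA receptor (7.94), Lcn2, which withholds iron from bacteria (7.66), Cp, a copper-carrying ferroxidase (7.53), and Cxcl5, which attracts neutrophils (7.37). The membrane mucin Muc1 rose by 6.94, Bicc1 by 6.58, Rdx by 6.35, the matrix proteins Efemp1 and Fn1 by 6.32 and 6.24, Plet1 by 6.15, the lipopolysaccharide-binding protein gene Lbp by 5.66 and Tnfaip2 by 5.62. At the other end stood the antimicrobial peptides Defa24 (-7.94), Defa3 and Defa17 (-7.26 each), Defa31 (-6.72) and Lyz1 (-6.95). The urea cycle enzyme Cps1 changed by -7.60, the sugar-splitting enzyme Sis by -7.22, Reg1 by -7.13, the fatty acid binding proteins Fabp2 and Fabp1 by -6.85 and -6.57, the brush border phosphatase Alpi by -6.68 and Far2 by -6.65. Gabrp, as an example of the levels behind these changes, stood at 12.56 ± 0.19 (SD, n = 5) in KO and 4.62 ± 0.34 (SD, n = 5) in WT. Defa24 stood at 4.30 ± 0.15 (SD, n = 5) in KO and 12.24 ± 0.16 (SD, n = 5) in WT. Reg1 spread most among these genes, with an SD of 2.11 in KO. Defa3 and Defa17 had identical values on all 10 arrays, so α-defensin paralogs were not resolved. Sizes measured against a level near the negative control medians, as for Gabrp in WT and Defa24 in KO, are lower bounds, and so is that of Lcn2, which held the highest value of its array in KO replicate 5.

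Over all genes, 5224 of 19572 probe sets paired with 1 gene changed, or 26.7% (limma, adjusted p under 0.05). 2928 were higher and 2296 lower in KO. Among them 1303 were higher and 953 lower by over 2-fold, and 199 were higher and 239 lower by over 8-fold. For 3989 of the changed probe sets the 5 KO and the 5 WT values did not overlap. Over all tested probe sets this held for 21.4%, where chance gives 0.794%. Against a change of at least 1.2-fold (limma's treat), 3034 probe sets passed. Spike-in control RNAs also differed between the groups, by a median of -0.52 and by at most 0.85 in size. This limits above all the reading of changes of that size or less, but it does not bound a batch effect on larger ones.

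Most markers on the fetal intestinal epithelium list rose in the KO organoids. Of the 31 measured members, 25 rose, 1 fell and 5 did not pass; adjusted over the list alone, 26 rose and 2 fell. The annexins Anxa1, Anxa3 and Anxa5, which bind membrane phospholipids, rose by 4.99, 4.83 and 4.04, the urokinase receptor Plaur by 3.76 and the secreted chaperone Clu by 4.95. Clu reached 13.20 ± 0.13 (SD, n = 5) in KO against 8.26 ± 1.04 (SD, n = 5) in WT. The member that fell, singled out after its values were seen, was Igf2bp3 (-2.69), an RNA-binding protein of fetal tissues; without KO replicate 2 or WT replicate 1, 2 members fell. The 5 that did not pass, also named after their values were seen, were Col4a1 (0.37), Anxa10 (-1.35), Lin28b (-0.13), Ccnd2 (-0.23) and Hmga2 (0.05). The list therefore did not rise in all its parts. As a set the list was higher in KO against all other genes (limma's camera, adjusted p = 1.12e-15), and it stayed past the threshold with an adjusted p = 0.029 with an estimated correlation. The same 5 KO arrays had the lower Y-linked signal. Ly6a, Spp1 and the adult stem cell marker Olfm4, which were fixed to be named, are unnamed here and were not analysed.

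Adult intestinal stem cell markers went both ways. Of 28 measured members 8 rose, 12 fell and 8 did not pass; adjusted over the list alone, 8 rose and 13 fell. The water channel Aqp4 (-4.49), the nuclear receptor Esrrg (-2.48) and the matrix protein Smoc2 (-1.91) fell, and the membrane protein Prom1 rose by 1.82. Lgr5, the receptor that marks crypt base stem cells, changed by -0.91 with a standard error of 0.52, which did not pass (limma, adjusted p = 0.236). Neither did the list as a set (limma's camera, adjusted p = 0.196; adjusted p = 0.834 with an estimated correlation). WT replicate 4 decided both: without it the list was lower in KO (limma's camera, adjusted p = 0.0221), and Lgr5 changed by -1.40 (limma, adjusted p = 0.0129).

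Array by array, the mean centred level of the fetal list was 1.21 ± 0.19 (SD, n = 5) in KO and -1.21 ± 0.24 (SD, n = 5) in WT. The difference was 2.42 (exact two-sided permutation test, p = 0.00794, the smallest these 10 arrays can give; adjusted over 3 comparisons, 0.0119). For the adult stem cell list the means were -0.20 ± 0.07 (SD, n = 5) and 0.20 ± 0.64 (SD, n = 5). The difference of -0.40 lay within the spread of the WT arrays (exact two-sided permutation test, p = 0.206). WT replicate 4 stood apart at -0.80, and the other WT arrays, at 0.14 to 0.92, lay above all KO arrays (-0.29 to -0.11). The fetal minus adult level differed by 2.81 between the groups (exact two-sided permutation test, p = 0.00794, again the smallest possible). All 5 KO arrays lay above all 5 WT arrays.

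**Figure D2:**
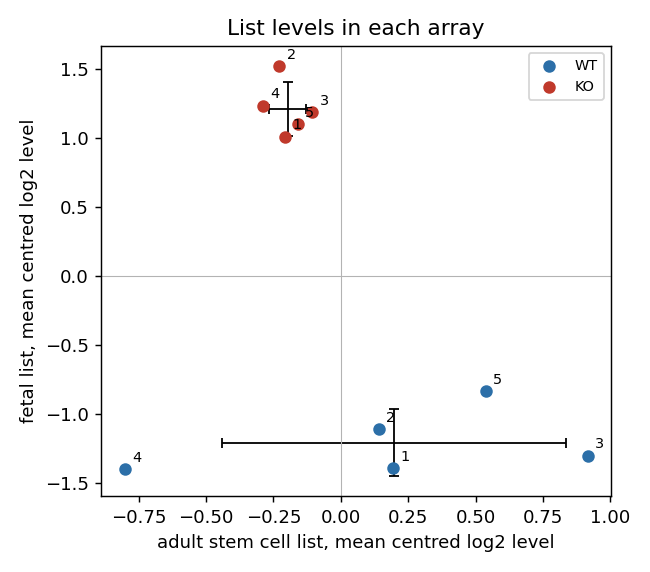
Mean centred log2 level of the adult stem cell list (horizontal) and of the fetal list (vertical) in each array, numbered by replicate; crosses give the group mean and SD. The groups separate on the fetal list, with WT replicate 4 lowest on the adult list.

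Genes that NF-kB switches on were higher in KO as a set with the preset correlation (limma's camera, adjusted p = 1.19e-10), but this was lost at an adjusted p = 0.0736 with an estimated correlation. Of 46 measured members 30 rose, 4 fell and 12 did not pass; adjusted over the list alone, 32 rose and 4 fell. Lcn2 and Cxcl5 led the list, and the chemokine Cxcl16 rose by 3.63. The members that fell were Nfkbia itself and, singled out after their values were seen, the antibody transporter Pigr (-3.70), the mitochondrial enzyme Sod2 (-0.86) and the proteasome subunit Psmb9 (-0.46). Psmb9 lost its call without any 1 of KO replicates 2 to 5 or WT replicates 1 to 4 (limma, adjusted p = 0.0725 to 0.116).

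Interferon response genes did not shift as a set (limma's camera, adjusted p = 0.195). Of 33 measured members 3 rose, 2 fell and 28 did not pass; adjusted over the list alone, 2 rose and 2 fell. Bst2, which tethers viruses to the membrane, rose by 2.54, the GTPase Gbp2 by 1.65 and Irf9, named after its value was seen, by 0.88. The interferon regulatory factor Irf8 (-1.52) and Ifi27l2a (-1.23) fell. Irf9 lost its call without KO replicate 5 or without any 1 of WT replicates 1, 2, 3 and 5 (limma, adjusted p = 0.0581 to 0.0809).

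Target genes of YAP, a transcriptional coactivator active in spread and regenerating epithelium, rose together. Of 28 measured members 21 rose, none fell and 7 did not pass; adjusted over the list alone, 23 rose and 1 fell. Ankrd1 rose by 5.52, the secreted matricellular proteins Ccn1 and Ccn2 by 3.93 and 3.79, and Fjx1 by 3.46. Without KO replicate 2 or WT replicate 3, 1 member fell. The set test gave an adjusted p = 1.95e-15 (limma's camera) and held with an estimated correlation (adjusted p = 0.0055). Stress and immediate early genes were higher as a set too (limma's camera, adjusted p = 3.55e-07; adjusted p = 0.214 with an estimated correlation). Of 30 measured members 16 rose, none fell and 14 did not pass, with the same 16 and 0 adjusted over the list alone. The phosphatase Dusp1 rose by 3.52, Ier3 by 3.41, the p53 target Trp53inp1 by 2.01 and the heat shock protein Hspa1b by 1.89.

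Genes of the Wnt and Notch pathways did not shift against other genes. Of 23 measured Wnt targets 5 rose, 2 fell and 16 did not pass, with 5 and 2 adjusted over the list alone (limma's camera, adjusted p = 0.694). The hyaluronan receptor Cd44 rose by 3.21 and the transcription factor Sox4 by 1.79; the stem cell and Paneth cell factor Sox9, the ligase Znrf3 (0.80) and Tcf4 (0.57) also rose and were named after their values were seen. The intestinal transcription factor Cdx1 (-3.01) and the stem cell factor Ascl2 (-1.01) fell. The Wnt count of 5 was 3 without KO replicate 3, 4 or 5 or WT replicate 2, and the count of 2 was 4 without WT replicate 4. Sox9 lost its call without any 1 of KO replicates 2 to 5 or WT replicates 1 and 2 (limma, adjusted p = 0.0539 to 0.0803), and Znrf3 without KO replicate 1, 3, 4 or 5 or WT replicate 2, 4 or 5 (limma, adjusted p of 0.0566 or more). Of 28 measured Notch pathway genes 10 rose, 6 fell and 12 did not pass; adjusted over the list alone, 10 rose and 7 fell (limma's camera, adjusted p = 0.186; limma's fry against no change, adjusted p = 0.00131). The coactivator Maml2 rose by 2.88, the receptor Notch2 by 1.47 and the ligand Jag1 by 1.42, and the target Nrarp changed by -1.13. Without WT replicate 3 or 5 only 3 Notch pathway genes fell.

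Paneth cell markers fell by a median of -4.99. Of 20 measured members 16 fell, 3 rose and 1 did not pass; adjusted over the list alone, 16 fell and 4 rose. Beside the α-defensins, the antimicrobial ribonuclease Ang4 fell by 6.45. The members that rose, singled out after their values were seen, were the protease Mmp7 (3.05), the surface protein Cd24a (1.29) and the stress-induced Nupr1 (1.16). The set test gave an adjusted p = 1.06e-15 (limma's camera) and held with an estimated correlation (adjusted p = 0.0289). Nupr1 lost its call without WT replicate 2 (limma, adjusted p = 0.0510).

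Enteroendocrine markers, the hormones and granule proteins of endocrine cells, fell without exception among those that passed. Of 28 measured members 22 fell, none rose and 6 did not pass; adjusted over the list alone, 23 fell and 0 rose. The granule proteins Chgb (-4.81), Chga (-2.79) and Scg2 (-2.80) and the hormones Tac1 (-4.20) and Cck (-3.62) were among them (limma's camera, adjusted p = 1.95e-15; adjusted p = 0.0478 with an estimated correlation). Goblet cell markers were also lower as a set (limma's camera, adjusted p = 4.27e-05; adjusted p = 0.360 with an estimated correlation). Of 26 measured members 17 fell, 1 rose and 8 did not pass; adjusted over the list alone, 18 fell and 1 rose. The secreted mucin Muc2 fell by 2.82, Klk1 by 4.98, Slc12a8 by 2.64 and Tspan13 as well (-1.83), and the calcium-binding S100a14 rose by 2.58. Without KO replicate 1, WT replicate 2 or WT replicate 5, 10 goblet cell markers fell. Tuft cell markers did not shift as a set (limma's camera, adjusted p = 0.286). Of 24 measured members 1 rose and 1 fell, the kinase Dclk1 (1.29) and Rgs13 (-1.28), with 0 and 0 adjusted over the list alone; Avil (-0.33) and Plcb2 (-0.25) did not pass. Avil passed without KO replicate 2 or WT replicate 3 (limma, adjusted p = 0.0276 and 0.0336), and 2 tuft cell markers fell without KO replicate 1. Dclk1 lost its call without KO replicate 4 or WT replicate 2 (limma, adjusted p = 0.0563 and 0.0542), and Rgs13 without any 1 of KO replicates 2 to 5 or WT replicates 2, 3 and 5 (limma, adjusted p = 0.0600 to 0.0740).

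Absorptive enterocyte genes were lower as a set with the preset correlation (limma's camera, adjusted p = 3.69e-23), but this was lost at an adjusted p = 0.115 with an estimated correlation. Of 34 measured members 31 fell, none rose and 3 did not pass, with the same 31 and 0 adjusted over the list alone; the median was -4.37. The lipid transfer protein Mttp, needed to assemble chylomicrons, fell by 5.76, beside Sis, Fabp2 and Alpi. Of 13 measured genes of the weaned enterocyte 12 fell, none rose and 1, the arginase Arg1 (0.28), did not pass, with 12 and 0 adjusted over the list alone. The glucose transporter Slc5a1 (-6.29), the arginase Arg2 (-5.43) and the starch-splitting enzyme Mgam (-4.94) were among them (limma's camera, adjusted p = 7.67e-12; adjusted p = 0.111 with an estimated correlation). Of 15 measured genes of the suckling enterocyte 8 fell, 1 rose and 6 did not pass; adjusted over the list alone, 8 fell and 3 rose. Cps1, the gluconeogenic enzyme Fbp1 (-4.71) and the milk sugar enzyme Lct (-1.91) fell, and the lysosomal protease Ctsl rose by 2.95. The suckling list passed (limma's camera, adjusted p = 0.0375; adjusted p = 0.395 with an estimated correlation), but not without KO replicate 3, WT replicate 4 or WT replicate 5 (adjusted p = 0.0709, 0.0709 and 0.0572), nor with the dimmest probe sets left out (adjusted p = 0.0721). Without KO replicate 4 or WT replicate 2, 5 of its genes fell, and without KO replicate 1, KO replicate 3 or WT replicate 3, 2 rose. These lower enterocyte levels, too, were in the arrays with the lower Y-linked signal.

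Genes of both ends of the small intestine were lower as sets by camera, though only with the preset correlation. Of 15 measured proximal genes 10 fell, 1 rose and 4 did not pass; adjusted over the list alone, 11 fell and 1 rose. The proximal transcription factor Gata4 fell by 3.47, the glucose transporter Slc2a2 by 5.42 and Adh6a by 6.06, and Onecut2, named after its value was seen, rose by 1.46, with 2 members higher without WT replicate 1 (limma's camera, adjusted p = 1.77e-07; adjusted p = 0.111 with an estimated correlation). Of 15 measured distal genes 8 fell, 1 rose and 6 did not pass; adjusted over the list alone, 9 fell and 2 rose. The peptide hormone Guca2b (-4.11), the bile acid exporter subunit Slc51a (-2.63) and Fgl2 (-1.89) fell, while Slc10a2, the bile acid importer of the ileum, rose by 4.54, with 2 members higher without WT replicate 4 (limma's camera, adjusted p = 0.00293; adjusted p = 0.395 with an estimated correlation). Of 17 measured genes of colon epithelium 5 fell, none rose and 12 did not pass, with 5 and 0 adjusted over the list alone. They were Ang4, the chloride exchanger Slc26a3 (-4.85), Mettl7b (-0.93), Slc37a2 (-0.69) and, named after its value was seen, Sycn (-0.33) (limma's camera, adjusted p = 0.0199; adjusted p = 0.279 with an estimated correlation). Sycn lost its call without KO replicate 3, 4 or 5 or WT replicate 2 (limma, adjusted p = 0.0602 to 0.0714). Stomach epithelium genes did not shift against other genes (limma's camera, adjusted p = 0.694; limma's fry against no change, adjusted p = 0.00437), with a median of -0.03 but a mean of 0.59. Of 24 measured members 4 rose, 2 fell and 18 did not pass, with 4 and 2 adjusted over the list alone. Beside Muc1, the trefoil peptide Tff2 rose by 4.25, the protease Ctse by 3.97 and Vsig1 by 3.24; Gkn3 (-1.62) and Cym (-0.90), named after their values were seen, fell. Without KO replicate 1, 3, 4 or 5 or WT replicate 2, 3 or 5, 1 member fell. Gkn3 lost its call when any 1 array other than KO replicate 2 or WT replicate 4 was left out (limma, adjusted p = 0.0621 to 0.0955).

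Metabolic lists were lower as sets by camera, though only with the preset correlation. Of 33 measured xenobiotic and glutathione genes 22 fell, 6 rose and 5 did not pass, with the same counts adjusted over the list alone. The cytochrome Cyp2c66 (-6.39), the export pump Abcc2 (-5.89), the esterase Ces2e (-5.13) and the glutathione transferase Gstm3 (-4.13) fell (limma's camera, adjusted p = 3.73e-08; adjusted p = 0.196 with an estimated correlation). Of 33 measured retinoid genes 13 fell, 6 rose and 14 did not pass; adjusted over the list alone, 14 fell and 6 rose. The retinol dehydrogenase Adh1 (-6.50), the retinol-binding Rbp2 (-4.47) and the storage enzyme Lrat (-2.25) fell, and the retinol receptor Stra6 rose by 3.14 (limma's camera, adjusted p = 0.0199; adjusted p = 0.438 with an estimated correlation). Of 19 measured cholesterol synthesis genes 11 fell, none rose and 8 did not pass; adjusted over the list alone, 15 fell and 1 rose. The sterol sensor Insig1 (-1.52), the sterol carrier Stard4 (-1.43) and the enzymes Lss (-0.83) and Idi1 (-0.82) led them (limma's camera, adjusted p = 0.000144; adjusted p = 0.395 with an estimated correlation).

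Whether cell cycle genes shifted depended on the test. As a set they were lower with the preset correlation (limma's camera, adjusted p = 0.000341), but not with an estimated one (adjusted p = 0.634), the correlation between members being 0.935, nor by limma's fry (adjusted p = 0.174). Of 35 measured proliferation genes 2 fell, none rose and 33 did not pass, with 0 and 0 adjusted over the list alone; the median was -0.78. The cyclin Ccne2 (-1.48) and the replication clamp Pcna (-0.78) passed, while the thymidine kinase Tk1 (-0.71), the spindle motor Kif11 (-1.72) and Mki67 (-1.44) did not. Mki67 spread widely in KO, at 8.92 ± 1.57 (SD, n = 5) against 10.36 ± 0.51 (SD, n = 5) in WT. Single arrays moved the count of 2 that fell: it was 14 without KO replicate 3, 6 without KO replicate 2 or WT replicate 4, 1 without WT replicate 5 and 0 without any 1 of the remaining 6 arrays. Ccne2 lost its call without KO replicate 1, 4 or 5 or WT replicate 1, 2 or 3 (limma, adjusted p = 0.0585 to 0.0703), and Pcna without these or WT replicate 5 (limma, adjusted p = 0.0799 to 0.108). Kif11 passed without KO replicate 2 or 3 or WT replicate 4 (limma, adjusted p = 0.0113 to 0.0375), Tk1 without KO replicate 2 or WT replicate 4 (limma, adjusted p = 0.0394 and 0.0055), and Mki67 without KO replicate 3 (limma, adjusted p = 0.0219).

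Genes of polycomb repressor complexes and of demethylases of histone H3 did not shift against other genes (limma's camera, adjusted p = 0.220). By limma's fry against no change, the adjusted p was 0.0417. Of 30 measured members 9 rose, 3 fell and 18 did not pass, with 9 and 3 adjusted over the list alone. The subunits Phc1, Phc2 and Phc3 rose by 1.11, 0.89 and 0.57, Jarid2 changed by -0.67 and, named after their values were seen, Suz12 by -0.55 and Pcgf5 by -0.42. The methyltransferase Ezh2 (-0.30) did not pass (limma, adjusted p = 0.391), but did without WT replicate 4 (limma, adjusted p = 0.0269). Pcgf5 lost its call without KO replicate 1, 3 or 5 or WT replicate 1 or 3 (limma, adjusted p = 0.0514 to 0.0583). Of 33 measured Hox genes, which set position along the body axis, 5 fell, none rose and 28 did not pass; adjusted over the list alone, 3 fell and 0 rose. Hoxa3 (-1.35), Hoxa5 (-1.11), Hoxa2 (-1.05), Hoxb8 (-0.41) and, named after its value was seen, Hoxa4 (-0.41) fell (limma's camera, adjusted p = 0.0103; adjusted p = 0.395 with an estimated correlation). Without any 1 array other than KO replicates 2 and 4 and WT replicate 3, 3 of them fell. Hoxa4 and Hoxb8 lost their calls without any 1 array other than KO replicate 2 and WT replicate 3 (limma, adjusted p = 0.0530 to 0.118).

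Genes of cell junctions and keratins were higher as a set (limma's camera, adjusted p = 0.00421; adjusted p = 0.196 with an estimated correlation). Of 28 measured members 15 rose, 4 fell and 9 did not pass; adjusted over the list alone, 16 rose and 5 fell. The laminin chain Lama3 rose by 4.36, the claudin Cldn4 by 2.61 and the keratin Krt7 by 2.23. The claudin Cldn15 fell by 5.68 and, named after their values were seen, Dsc2 by 0.90, Pkp2 by 0.55 and Cldn7 by 0.46.

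Markers of cell types other than epithelium did not shift against other genes. Of 24 measured mesenchymal genes Fn1 rose, the proteoglycan Lum fell by 0.39 and 22 did not pass, with 1 and 1 adjusted over the list alone; the median was 0.00 (limma's camera, adjusted p = 0.789). Col5a1 (0.50) and Vim (-0.53) were among those that did not pass; Col5a1 passed without KO replicate 1 or WT replicate 4 (limma, adjusted p = 0.0188 and 0.0197) and Vim without WT replicate 1 (limma, adjusted p = 0.00913). In counts, 2 members rose without KO replicate 1, KO replicate 4 or WT replicate 4, and 2 fell without KO replicate 1 or WT replicate 1. Of 17 measured endothelial genes 3 rose, 1 fell and 13 did not pass, with 3 and 1 adjusted over the list alone (limma's camera, adjusted p = 0.930). The transcription factors Sox17 (1.33) and Ets1 (1.24) and the receptor Flt1 (0.84) rose, and the hyaluronan receptor Lyve1 changed by -1.92; 2 genes fell without WT replicate 4. Of 24 measured immune genes 2 rose, 3 fell and 19 did not pass, with 2 and 3 adjusted over the list alone (limma's camera, adjusted p = 0.322; limma's fry against no change, adjusted p = 0.00664). The integrin Itgam (1.56) and the receptor Csf1r (1.53) rose; the lysozyme Lyz2 (-4.18), the actin bundler Lcp1 (-2.76) and, named after its value was seen, Coro1a (-0.44) fell. Coro1a lost its call without KO replicate 4 or WT replicate 5 (limma, adjusted p = 0.0547 and 0.0544). Of 13 measured genes of enteric neurons and glia 2 rose, 1 fell and 10 did not pass, with 2 and 1 adjusted over the list alone (limma's camera, adjusted p = 0.787). The receptor Ret (0.90) and S100b (0.46) rose, the synaptic Snap25 (-0.79) fell, and Erbb3 (-0.42) did not pass; 2 genes fell without WT replicate 3.

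**Figure D3:**
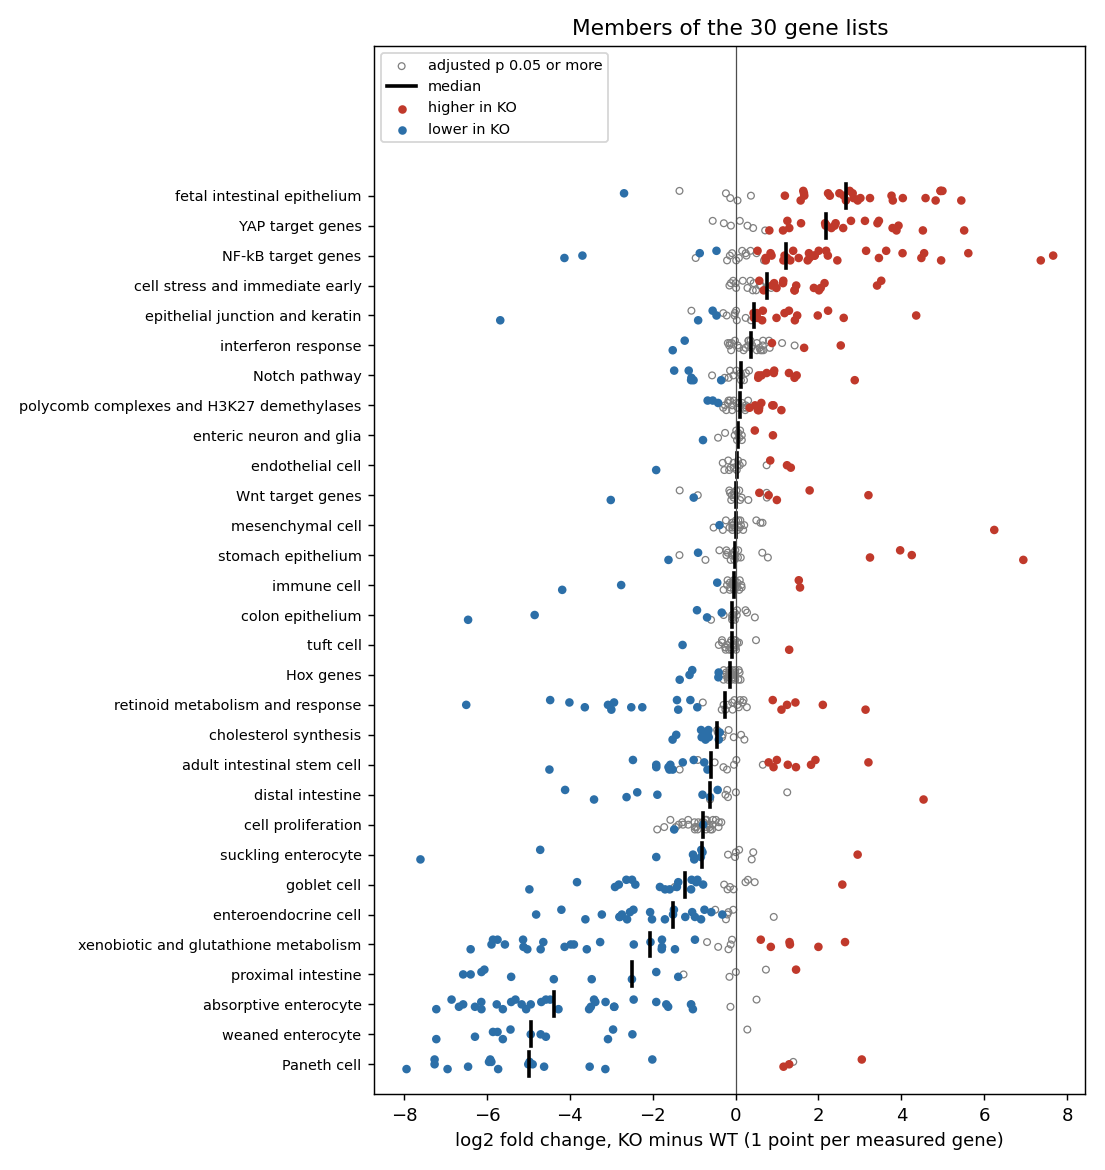
Change (log2, KO minus WT) of each measured member of the 30 gene lists, 1 point per gene, with the list median as a black bar; filled points passed limma's adjusted p of 0.05, red higher and blue lower in KO. Most fetal, YAP target and NF-kB target genes lie to the right, and most Paneth cell and enterocyte genes to the left.

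In all, 19 of the 30 lists shifted against the other genes, 5 higher and 14 lower in KO (limma's camera with a preset correlation, adjusted p under 0.05). Some of these lists, the enterocyte, regional and metabolic ones among them, shared members, so they are not 19 separate results. With an estimated correlation 4 lists passed, the fetal and YAP target lists higher and the Paneth and enteroendocrine lists lower. By limma's fry, which asks whether the genes of a list move and sets them against no other genes, 22 lists moved on balance in 1 direction and 29 held changes in either direction (adjusted p under 0.05).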

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

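Of 396 groups of 5 values checked by the ratio of gap to range, 20 passed the bound, where chance gives about 1 in 20 or 19.8. 7 of the 20 were values of WT replicate 4, and 4 were of KO replicate 1. WT replicate 4 was lower than the other WT arrays in Defa3 and Defa17 (ratio 0.855 each, 12.25 against 12.48 to 12.52), Defa31 (0.921), Far2 (0.830, 10.54 against 11.40 to 11.58) and Kdm5d (0.769, 4.92 against 6.26 to 6.66). It was higher in Ankrd1 (0.846) and Insig1 (0.914, 11.87 against 11.02 to 11.10). KO replicate 1 stood apart in Gbp2 (0.725, 7.24 against 5.24 to 5.79), Itgam (0.773, 8.37 against 6.14 to 6.64), Psmb9 (0.794) and Plcb2 (0.766). The others were Nfkbia in WT (0.730, replicate 5), Chgb and Chga in WT (0.714 and 0.758, replicate 1), Lyz1, Stra6 and Myo1a in KO (0.834, 0.723 and 0.739, replicate 4), Tnc in KO (0.736, replicate 5), Ush1c in KO (0.776, replicate 3) and Znrf3 in KO (0.735, replicate 2). No array was removed from the comparison. Of the 2634 probe sets unnamed here, 405 changed, 215 higher and 190 lower in KO (limma, adjusted among themselves).

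The tests of whether sex causes the other changes, and of X-linked genes by fry and without Kdm6a, were chosen only after the result was seen; the bound for X-linked genes was written before. Y-linked transcripts were low in every KO array. This may mean that the KO cultures are XX and the WT cultures XY, or that XY cultures lost the Y chromosome. Xist and Ddx3y, also on the sex-linked list, are unnamed here and were not read. The 5 X-linked genes that escape inactivation had a median change of 0.23, past the bound of 2 SE written in advance for XX cultures if the SE of their mean change is used (mean 0.23, SE 0.096; exact permutation test, p = 0.0635). The set moved by limma's fry, which tests against no change (adjusted p = 0.027), but not against other genes (limma's camera, adjusted p = 0.209). The value of Kdm6a had been seen before, and the other 4 genes did not pass by fry (limma, adjusted p = 0.179), so the bound was too lenient and the explanations cannot be told apart. With X and Y probe sets left out, 5065 probe sets changed, a count that does not test sex: since Y-linked signal was low in all KO arrays and in no WT array, effects of sex or of cell line cannot be told apart from those of the genotype.

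The tests of mesenchymal cells, of stomach epithelium and of the deletion were chosen only after the result was seen; those of Cdx2 and of unseen duct genes were written before. Most fetal markers, Fn1 and some duct and stomach genes rose while enterocyte genes fell, which might come from other cells in the KO cultures. Mesenchymal genes without Fn1 had a median of -0.0095 (SE 0.074), which argues against mesenchymal cells. Stomach genes had one of -0.026 (SE 0.51), just past the bound written for this test, 2 SE below a change of 1. That bound was set aside, because members went both ways (Muc1 6.94, Gkn3 -1.62). The median therefore decides nothing, and stomach-like epithelium stays open. Cdx2, which holds intestinal identity, changed by -2.16, between the bounds set for loss and for keeping of that identity, and the 10 duct genes not seen before had a median of 0.43 (SE 0.76), so a duct-like epithelium stays open. The loss of Nfkbia (-4.13) could also be the cause, and these cannot be told apart while the Y-linked difference moves with the genotype.

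The tests of spike-in controls and of batches were chosen only after the result was seen; that of random splits was written before. Of the 126 possible splits of the 10 arrays, 100 were drawn. Only the real one gave as many as 5224 changed probe sets, and the highest other gave 403. The arrays formed 2 groups, so any other split mixed them. The test therefore cannot exclude a chance difference between 2 animals, lines or cultures. The 8 spike-in controls were all lower in KO, by a median of -0.52 and by at most 0.85 in size. None differed by over 1 on the log2 scale, which argues against a difference of that size, for these 8 controls only. Whether their difference arose in labelling or in hybridisation was not tested. Single negative and positive controls differed by up to 1.94 and 1.91 in size. Of the 5222 negative ones 5 passed, and 624 had a p under 0.05 before adjustment (limma). Among the 1324 positive controls 17.6% changed, but on arrays of this kind such controls usually target transcripts of the sample. No batch is recorded, and 8 spike-in controls cannot bound a batch effect on other probe sets. A difference between batches of arrays therefore cannot be told apart from the genotype, whatever the size of the change.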

How the results depend on the processing

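Nfkbia, the fetal list and the NF-kB list kept direction under each alternative run for them. No named gene was reversed under the alternatives run for single genes, but some calls changed. Of 194 genes, 5 lost and 3 gained a call with replicate number as a block, and as many with centring on the 75th percentile. With cyclic loess 2 lost and 4 gained a call, and with array weights 1 lost and 6 gained it. Leaving out control or X and Y probe sets, the wider adjustment and the 1.2-fold test were run for the count only. Leaving out 1 array moved Nfkbia between -4.20 and -3.96, the count of changed probe sets between 4344 (without WT replicate 2) and 5187 (without KO replicate 2), and the number of changed lists between 18 and 19. The adult stem cell list ranged from an adjusted p of 0.0221 (limma's camera, without WT replicate 4) to 0.396 (without WT replicate 3). It reached 0.0403 with KO replicate 2 and WT replicate 4 left out, an alternative added after the data were seen. The count fell to 3034 when tested against a 1.2-fold change (1772 higher, 1262 lower), and lay between 4869 and 6182 under the other alternatives that kept all 10 arrays. With an estimated correlation 4 lists passed, and the NF-kB list did not (limma's camera, adjusted p = 0.0736). With replicate number as a block, the array-level fetal minus adult difference stayed 2.81 with an exact permutation p of 0.0625, the smallest possible for 5 pairs. Whether equal numbers are pairs is not settled, since deviations from the group mean correlated between them by -0.07 to 0.36. The best match of a KO array was the WT array of equal number for replicates 3 and 4 only.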

Other observations

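7 lists were written after the data were seen, and some of their members were chosen because they had already stood out. Apart from the X-linked list, whose set was also tested in full, the set tests given for them therefore ran only on members whose values had not been seen when the list was written. This does not undo the choice of the themes from these same arrays, and unseen members can move with seen ones. These set tests are therefore not independent support. Genes of integrins and extracellular matrix, which anchor epithelium to its support, were higher as a set: of 21 measured members 18 rose, 1 fell and 2 did not pass, with 19 and 1 adjusted over the list alone. The protease inhibitors Timp2 (5.38) and Timp3 (3.90), thrombospondin Thbs1 (4.18), the collagen Col18a1 (3.77), tenascin Tnc (2.67) and the integrin Itgav (1.58) rose, and Fbln1 fell by 3.19. The 16 members not seen before were higher by a median of 1.94 (limma's camera, adjusted p = 6.38e-09; adjusted p = 0.00128 with an estimated correlation). Of 19 acute phase, complement and antimicrobial genes 7 rose, 1 fell and 11 did not pass, with 7 and 1 adjusted over the list alone. Beside Cp, Lcn2 and Lbp, whose rise had prompted the list, the lipopolysaccharide receptor Cd14 rose by 4.70 and Pglyrp1 by 1.53, and the lectin gene Reg3g fell. The 16 members not seen before did not shift against other genes (limma's camera, adjusted p = 0.135; limma's fry against no change, adjusted p = 0.00218). Hp, the haemoglobin-binding protein gene, rose by 1.26 but not without KO replicate 5 or WT replicate 2, 3 or 5 (limma, adjusted p = 0.0514 to 0.0614). Of 15 genes of bile and pancreatic ducts 9 rose, 2 fell and 4 did not pass, with 9 and 2 adjusted over the list alone. Pkhd1 rose by 4.30 and Hhex by 3.94, Onecut1 rose too, and the chloride channel Cftr fell by 1.98. Of the 10 members not seen before 5 rose, 1 fell and 4 did not pass, and they were higher as a set with the preset correlation (limma's camera, adjusted p = 0.00618; adjusted p = 0.0786 with an estimated correlation).

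Genes of intestinal identity, of the mature brush border and of fatty acid oxidation were lower as sets by camera, though only with the preset correlation. Of 14 identity genes 12 fell and 2 did not pass, with 12 and 0 adjusted over the list alone. Hnf4g fell by 4.55, Tm4sf5 by 4.64, the antigen gene Gpa33 by 2.20 and the cadherin Cdh17 by 0.68; the set test of 10 members not seen before gave an adjusted p = 4.94e-06 (limma's camera; adjusted p = 0.111 with an estimated correlation). Of 11 brush border genes 8 fell, 1 rose and 2 did not pass, with 8 and 1 adjusted over the list alone. The motor Myo1a (-3.56), the link protein Cdhr2 (-3.45) and its partner Ush1c (-2.93) fell (limma's camera, adjusted p = 8.68e-05; adjusted p = 0.143 with an estimated correlation). Ezr, an actin linker, rose by 0.32, but not without KO replicate 1 or 2 or WT replicate 2 or 3 (limma, adjusted p = 0.0520 to 0.0569). Of 16 genes of fatty acid oxidation 13 fell and 3 did not pass, with 13 and 0 adjusted over the list alone. The enzymes Ehhadh (-3.80) and Hadhb (-1.29) and the regulators Ppara (-2.93) and Creb3l3 (-3.33) fell (limma's camera, adjusted p = 1.96e-06; adjusted p = 0.143 with an estimated correlation). Of the 5 X-linked genes that escape inactivation Kdm6a rose by 0.47, but not without KO replicate 1, 4 or 5 or WT replicate 1, 2 or 5 (limma, adjusted p = 0.0796 to 0.0960), and Eif2s3x (0.24), Kdm5c (0.23), Pbdc1 (0.16) and Ddx3x (0.05) did not pass. Kdm5c passed without KO replicate 5 (limma, adjusted p = 0.0410).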
